A study of Rattus norvegicus with 167 samples.

How the data were processed

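All 167 arrays of the series were used, in 55 groups of 3 and 1 group of 2. The uninjured cords were 1 of these groups, and segment, treatment and day in the deposited labels defined the others. Per the submitters' processing notes, images were read with GCOS and values were computed by RMA in Affymetrix Expression Console. Which arrays were normalised together is not stated. The authors' deposited table holds log2 values for 31099 probe sets, and these were used as they stand. They ran from 2.63 to 15.0, with array medians from 7.10 to 7.25, and the highest correlation between 2 arrays was 0.998.

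Of the probe sets, 57 were controls, 21268 were in the annotation of the array, 20832 of these had 1 gene symbol, 436 had several and were left out, and 9780 had none. Symbols were compared through gene identifiers with the RefSeq annotation of assembly GRCr8, used for names alone: 20764 probe sets matched and 0 symbols changed. For each of 14218 genes the probe set with the highest mean was kept, and 4291 of the tested genes had more than 1. A gene was tested if it lay above the 40th percentile of its array in at least 3 arrays, which kept 12040 genes. The gene for neurotrophin-3, Ntf3, lay below that filter.

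Group means were fitted with limma 3.58.1 in R 4.3.3, one fit for each segment together with the uninjured cords, and both segments together for comparisons between segments. Contrasts of group means gave LC against uninjured cord in 3 periods, NT3 against LC, NT3 against ET and ET against LC as means over the days that both had, NT3 against LC on day 3 at the lesion site, rostral against caudal LC, and the difference of the NT3 effect between these segments. A moderated F-test asked whether NT3 minus LC changed with the day. Moderated p-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as threshold. Comparisons share controls, since the same uninjured cords serve every injury comparison and the same LC arrays serve NT3 and ET, so no overlap between comparisons was computed.

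Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01 and adjusted over the 30 lists of a comparison, and again with an estimated correlation. The lists, written from general knowledge, were cytokines and chemokines, microglia and macrophage, complement, T cell, B cell and plasma cell, neutrophil, antigen presentation, interferon response, cell cycle, endothelium and angiogenesis, extracellular matrix and fibrosis, chondroitin sulfate proteoglycans, astrocyte, oligodendrocyte and myelin, oligodendrocyte precursor, neuron, synaptic transmission, motor neuron, neurotrophic factors and receptors, neural progenitor and neurogenesis, axon growth, Schwann cell, ependyma and cilia, skeletal muscle, erythrocyte, adipocyte, dorsal root ganglion neuron, immediate early, hypoxia and glycolysis, and cholesterol synthesis. Counts of members are given over all genes and, where different, adjusted over the list alone. Levels of a list are means over its tested members relative to uninjured cord.

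Named genes followed a rule set before the data were seen, like lists, comparisons and first alternatives. It took the 6 highest and 6 lowest called genes with the same sign on every day, up to 3 called members of each called list, and always Ntf3, Ntrk3, Ntrk2, Ngfr, Bdnf, Gfap, Aif1, Cd68, Mbp and Snap25. Genes outside it are marked, save in tests by day, which it did not cover.

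The alternatives were no filter, a filter at the 60th percentile, quantile normalization, scaling to the 75th percentile, the mean of probe sets, one fit of all arrays, a fit of the compared groups alone, array weights, a trended and robust prior, the replicate number as a block, days 10 to 90 for NT3 against LC, camera with an estimated correlation, and each array left out in turn. Chosen after seeing the data were covariates for the beta-actin difference and for the skeletal muscle list, the removal of 3 arrays that stood apart (LC day 20 replicate 5 and NT3 day 3 replicate 1 at the lesion site, and uninjured replicate 2), and the days on which RT1-CE10 was alike in the groups compared.

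The procedure was tested on simulated data with 200 of 12040 genes changed in the layout of 7 comparisons. Of 67, 67 and 66 genes changed by 0.3, 0.6 and 1.2, it recovered 57, 66 and 66 for NT3 against LC rostrally. For early injury rostrally it recovered 18, 55 and 66. It recovered 8, 53 and 64 for 3 against 3 arrays, and 2, 36 and 61 for the test by day at the lesion site. False calls numbered 2 to 10, and in the 6 comparisons with a direction 0 genes were called in the wrong one. A shift of the neuron list by 0.3 was found in all 6 comparisons tested, with 0 other lists called. This does not vouch for real list calls, of which 81 of 103 ended with an estimated correlation. Array weights gave 9 false calls instead of 10 for NT3 against LC rostrally, and 2 again by day.

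Probe sets without a name were tested for 2 comparisons alone, and raw array images were not analysed.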

Results

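The deposited values covered Affymetrix arrays of spinal cord from adult female Wistar rats with a complete mid-thoracic transection and removal of a 5 mm segment. Animals received a chitosan tube loaded with neurotrophin-3 (NT3), an empty tube (ET) or no tube (lesion control, LC), and 3 uninjured cords served as reference. Tissue rostral to the lesion, at the lesion site and caudal to it was taken on days 1, 3, 10, 20, 30, 60 and 90, the lesion site from day 3 on and with ET on day 3 alone. Arms held 21 NT3, 20 ET and 21 LC arrays rostrally, 21 of each caudally, and 18 NT3, 18 LC and 3 ET arrays at the lesion site. With the uninjured cords they made 55 groups of 3 and 1 group of 2. The number of arrays limits the precision. The labels do not say that replicates were separate animals, so p-values measure only the spread between these samples. Of 14218 genes with a named probe set, 12040 were tested. Numbers in brackets are differences in the authors' deposited log2 values, with the standard error (SE). Early, intermediate and late injury comparisons set LC on days 1 and 3, days 10 to 30, and days 60 and 90 against the same 3 uninjured cords.

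Rostral to the lesion, genes of leukocyte recruitment rose steeply in the first days of LC, led by the monocyte chemokine gene Ccl2 (6.89, SE 0.26, 2 of 2 days, adjusted p = 3.2e-27). The protease inhibitor genes Serpina3n (5.42, SE 0.33) and Timp1 (5.38, SE 0.18) and the acute phase gene Lbp (5.64, SE 0.27) rose with it. Genes of neurons fell, among them the AMPA receptor gene Gria3 (-1.56, SE 0.12) and the chloride transporter gene Slc12a5 (-1.46, SE 0.13). The astrocytic mitochondrial carrier gene Slc25a18 (-2.55, SE 0.18) and the kelch gene Klhdc7a (-2.80, SE 0.18) fell further. Members of the cytokine list rose (19 of 21 higher, mean 2.46, adjusted p = 1.4e-06, or 0.188 with an estimated correlation). Microglia and macrophage genes did too (21 of 23 higher, mean 2.15, adjusted p = 8.5e-13), with Cd68 (3.53, SE 0.20) and Aif1 (1.64, SE 0.16). Complement genes rose (11 higher and 1 lower of 12, mean 1.84, adjusted p = 7.8e-07). So did cell cycle genes (25 of 25 higher, mean 1.95, adjusted p = 2.4e-13, or 0.149 with an estimated correlation), for instance Cdk1 (3.33, SE 0.18). Myelin genes fell (18 of 19 lower, 19 adjusted over the list alone, mean -0.85, adjusted p = 2.9e-07, or 0.149 with an estimated correlation), with Gal3st1 (-1.23, SE 0.09). Neuron genes fell as a list (21 of 22 lower, mean -1.11, adjusted p = 1.4e-08, or 0.186 with an estimated correlation). Immediate early genes rose (15 higher and 1 lower of 18, mean 1.81, adjusted p = 2.7e-07, or 0.149 with an estimated correlation), with the stress factor gene Atf3 (4.50, SE 0.16). Astrocyte genes went both ways (5 higher and 10 lower of 17, mean 0.00, adjusted p = 0.195), and their median of -0.62 differed in sign from their mean. The neurotrophin receptor genes Ntrk2 (-0.78, SE 0.11) and Ntrk3 (-1.10, SE 0.14) fell, and Bdnf (0.00, SE 0.14, 1 of 2 days, adjusted p = 0.983) was not called. In limma 8157 of 12040 genes were called, 4332 higher and 3825 lower, of which 1245 rose and 746 fell at least 2-fold. The 3 uninjured arrays had a beta-actin difference between 3-prime and 5-prime probe sets of 1.72 (SD 0.51), against 1.07 (SD 0.22) in rostral LC.

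On days 10 to 30 the rostral segment of LC was dominated by phagocyte genes, with the Fc receptor-like gene Fcrl2 (5.75, SE 0.17, 3 of 3 days, adjusted p = 2.7e-31), the beta-glucan receptor gene Clec7a (5.09, SE 0.19) and the lysosomal gene Cd68 (4.90, SE 0.18) highest. The lysosomal glycoprotein gene Gpnmb (4.90, SE 0.11) and the macrophage elastase gene Mmp12 (4.88, SE 0.52) rose as well, while Ccl2 (3.71, SE 0.24) stood lower than in the first days. The lipid desaturase gene Scd (-2.55, SE 0.12, 3 of 3 days, adjusted p = 9.5e-23) fell most, with the positional genes Hoxa10 (-2.32, SE 0.31) and Hoxd9 (-1.84, SE 0.31). All microglia and macrophage genes rose (23 of 23 higher, mean 2.43, adjusted p = 3.7e-23). All complement genes did so (12 of 12 higher, mean 1.82, adjusted p = 8.6e-10), and so did antigen presentation genes (16 of 16 higher, mean 1.40, adjusted p = 3.0e-10). T cell genes rose (8 of 13 higher, mean 0.70, adjusted p = 0.0101, or 0.313 with an estimated correlation), with Cd8a (2.93, SE 0.27). All cholesterol synthesis genes fell (16 of 16 lower, mean -1.22, adjusted p = 4.1e-13), with Sqle (-1.43, SE 0.09) and Fdft1 (-1.44, SE 0.08) as examples. Extracellular matrix genes stayed up (24 of 25 higher, mean 2.13, adjusted p = 1.6e-12, or 0.19 with an estimated correlation). Neuron genes stayed down (21 of 22 lower, mean -0.89, adjusted p = 3.0e-08, or 0.191 with an estimated correlation). The astrocyte filament gene Gfap (0.46, SE 0.05, 3 of 3 days, adjusted p = 2.4e-11) rose little. In limma 7281 genes were called, 3507 higher and 3774 lower, with 931 rising and 346 falling at least 2-fold. The larger direction turned after 75th percentile scaling (3865 higher and 3438 lower), with the mean of probe sets (3585 and 3327), with the beta-actin covariate (3574 and 2963) and without uninjured replicate 2 (3249 and 3176).

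On days 60 and 90 the phagocyte genes of rostral LC remained up, with Gpnmb (5.07, SE 0.11, 2 of 2 days, adjusted p = 3.8e-36), Fcrl2 (5.57, SE 0.18), Clec7a (5.30, SE 0.20) and Cd68 (4.98, SE 0.20). Lipid synthesis stayed down, with Scd (-2.88, SE 0.13, 2 of 2 days, adjusted p = 1.2e-23) and the squalene and isoprenoid enzyme genes Sqle (-1.74, SE 0.10) and Idi1 (-1.83, SE 0.12). Microglia and macrophage genes rose (23 of 23 higher, mean 2.25, adjusted p = 2.2e-25), as did complement genes (9 of 12 higher, mean 1.46, adjusted p = 2.0e-08). Antigen presentation genes rose (15 of 16 higher, mean 1.38, adjusted p = 2.4e-11). All cholesterol synthesis genes fell (16 of 16 lower, mean -1.38, adjusted p = 8.2e-17). Cell cycle genes were still up in part (15 of 25 higher, mean 0.48, adjusted p = 0.00238, or 0.593 with an estimated correlation). Neuron genes stayed lower (21 of 22 lower, mean -0.74, adjusted p = 4.3e-07, or 0.272 with an estimated correlation). The positional genes Hoxa10 (-2.73, SE 0.33, 2 of 2 days, adjusted p = 9.7e-10) and Hoxd9 (-2.21, SE 0.33) were lower than in uninjured cord. In limma 6453 genes were called, 2999 higher and 3454 lower, with 807 rising and 186 falling at least 2-fold. With the mean of probe sets the split was 3095 higher and 3067 lower, and with the beta-actin covariate 3186 and 2828.

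At the lesion site on day 3 of LC, inflammation and matrix genes rose together, with Lbp (7.30, SE 0.17, adjusted p = 3.1e-26), the neutrophil chemokine gene Cxcl2 (7.04, SE 0.42) and Ccl2 (6.94, SE 0.19). So did the matrix gene Tnc (6.56, SE 0.21) and the collagen cross-linking gene Lox (6.36, SE 0.16). Genes of neurons fell, for example the inhibitory vesicle transporter gene Slc32a1 (-4.27, SE 0.34), the acetylcholine synthesis gene Chat (-3.13, SE 0.19) and the neuronal gene Olfm3 (-4.88, SE 0.38, adjusted p = 3.8e-13). The astrocyte gene Gfap (-1.35, SE 0.44, adjusted p = 0.0062) and the myelin gene Mbp (-0.75, SE 0.19) fell, and the low-affinity neurotrophin receptor gene Ngfr (1.73, SE 0.29, adjusted p = 3.3e-06) rose. All extracellular matrix genes rose (25 of 25 higher, mean 3.96, adjusted p = 1.3e-15). Cytokine genes rose too (16 of 21 higher, mean 2.87, adjusted p = 7.6e-05, or 0.138 with an estimated correlation). Hypoxia genes followed them (14 higher and 2 lower of 18, mean 1.45, adjusted p = 0.00395, or 0.364 with an estimated correlation). Every myelin gene fell (19 of 19 lower, mean -2.47, adjusted p = 3.0e-06, or 0.364 with an estimated correlation). So did every ependymal gene (8 of 8 lower, mean -1.25, adjusted p = 0.00698, or 0.364 with an estimated correlation). Muscle genes were uneven (8 higher and 2 lower of 20, mean 1.54, adjusted p = 0.62). Erythrocyte genes stood higher without a call for the list (6 of 7 higher, mean 2.02, adjusted p = 0.0869). In limma 8952 genes were called, 4916 higher and 4036 lower, with 2285 rising and 1878 falling at least 2-fold.

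On days 10 to 30 genes of macrophages, lymphocytes and collagen were high at the lesion site of LC, with Mmp12 (8.78, SE 0.18, 3 of 3 days, adjusted p = 2.2e-28), the matrix gene Postn (7.56, SE 0.16) and the collagen gene Col1a1 (5.25, SE 0.10) among the largest rises. The lipid binding gene Fabp4 (6.72, SE 0.21), made by macrophages and fat cells, also rose. Neuron genes were low, with the sodium channel gene Scn1a (-6.55, SE 0.53, 3 of 3 days, adjusted p = 6.7e-13), the serotonin receptor gene Htr2c (-6.47, SE 0.59) and the synaptic gene Snap25 (-4.45, SE 0.57) far below uninjured cord. All cytokine genes rose (21 of 21 higher, mean 3.23, adjusted p = 6.3e-07, or 0.0906 with an estimated correlation). T cell genes rose likewise (13 of 13 higher, mean 2.09, adjusted p = 5.8e-05, or 0.13 with an estimated correlation), and matrix genes (25 of 25 higher, mean 4.32, adjusted p = 6.2e-16). The B cell list had every member higher, yet no call (6 of 6 higher, mean 1.50, adjusted p = 0.234). All neuron genes fell (22 of 22 lower, mean -3.89, adjusted p = 8.4e-08, or 0.269 with an estimated correlation). Motor neuron genes fell without exception (10 of 10 lower, mean -3.20, adjusted p = 0.00107, or 0.254 with an estimated correlation). Chondroitin sulfate proteoglycan genes went both ways (4 higher and 5 lower of 12, mean -0.71, adjusted p = 0.596). Oligodendrocyte precursor genes did too (3 higher and 4 lower of 8, mean -0.95, adjusted p = 0.579). The receptor genes Ntrk2 (-2.49, SE 0.26) and Ntrk3 (-1.88, SE 0.20) fell. In limma 9511 genes were called, 5049 higher and 4462 lower, with 2131 rising and 1930 falling at least 2-fold. The median difference over all genes was 0.07 as deposited, 0.10 under quantile normalization and 0.11 under 75th percentile scaling.

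On days 60 and 90 Mmp12 (8.28, SE 0.19, 2 of 2 days, adjusted p = 9.3e-27) and Postn (6.17, SE 0.17) still led the lesion site of LC, now with the lymphoid chemokine gene Ccl21 (6.52, SE 0.29). The water channel gene Aqp1 (6.05, SE 0.26) and the class II genes RT1-Db1 (4.38, SE 0.21) and Cd74 (3.22, SE 0.15) were high. The GABA synthesis gene Gad1 (-6.26, SE 0.44, 2 of 2 days, adjusted p = 2.7e-14), Scn1a (-6.14, SE 0.56) and Snap25 (-4.00, SE 0.60) stayed low, and Gfap (-0.68, SE 0.38, 2 of 2 days, adjusted p = 0.105) was not called. Matrix genes rose throughout (25 of 25 higher, mean 3.80, adjusted p = 1.9e-16). So did complement genes (12 of 12 higher, mean 2.73, adjusted p = 2.9e-06). Antigen presentation genes were up (15 of 16 higher, mean 2.36, adjusted p = 1.1e-06, or 0.122 with an estimated correlation). Synaptic genes were down (16 of 18 lower, mean -2.92, adjusted p = 1.7e-06, or 0.122 with an estimated correlation). Neurotrophic factor genes went both ways (5 higher and 10 lower of 15, mean -0.32, adjusted p = 0.552). In limma 9083 genes were called, 4870 higher and 4213 lower, with 1953 rising and 1759 falling at least 2-fold.

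Caudal to the lesion the first days of LC brought high Ccl2 (6.82, SE 0.36, 2 of 2 days, adjusted p = 1.5e-21) and Slpi (5.78, SE 0.31). The iron-binding gene Lcn2 (5.63, SE 0.38), Timp1 (5.49, SE 0.20) and the reactive astrocyte gene Serpina3n (5.45, SE 0.27) rose as well. The neurotrophin gene Bdnf (0.68, SE 0.16, 2 of 2 days, adjusted p = 2.1e-04) rose here, and the amino acid transporter gene Slc7a10 (-1.99, SE 0.17) and Klhdc7a (-2.91, SE 0.19) fell. All cell cycle genes rose (25 of 25 higher, mean 1.80, adjusted p = 1.3e-15, or 0.0869 with an estimated correlation). Cytokine genes rose in part (17 of 21 higher, mean 2.28, adjusted p = 3.7e-07, or 0.124 with an estimated correlation). All myelin genes fell (19 of 19 lower, mean -0.87, adjusted p = 1.6e-08, or 0.147 with an estimated correlation). Neuron genes went the same way (21 of 22 lower, mean -0.74, adjusted p = 2.8e-06, or 0.285 with an estimated correlation). In limma 7829 genes were called, 4130 higher and 3699 lower, with 1103 rising and 420 falling at least 2-fold. After 75th percentile scaling the split was 3918 higher and 3964 lower. The beta-actin difference was 1.00 (SD 0.16) in caudal LC, against 1.72 (SD 0.51) in uninjured cord.

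By days 10 to 30 the phagocyte genes Fcrl2 (5.84, SE 0.16, 3 of 3 days, adjusted p = 4.3e-33), Clec7a (5.28, SE 0.17), Cd68 (5.05, SE 0.24) and Gpnmb (4.95, SE 0.12) led the caudal segment of LC, and Scd (-2.71, SE 0.11, 3 of 3 days, adjusted p = 2.6e-26) fell most. Every microglia and macrophage gene rose (23 of 23 higher, mean 2.54, adjusted p = 4.7e-23). Antigen presentation genes rose alike (16 of 16 higher, mean 1.47, adjusted p = 7.7e-10). All cholesterol synthesis genes fell (16 of 16 lower, mean -1.38, adjusted p = 1.6e-13), with Hsd17b7 (-1.87, SE 0.12). Neuron genes fell (21 of 22 lower, mean -0.91, adjusted p = 3.1e-08, or 0.164 with an estimated correlation), the chloride transporter gene Slc12a5 (-1.31, SE 0.13) among them. In limma 7427 genes were called, 3512 higher and 3915 lower, with 960 rising and 405 falling at least 2-fold. The larger direction turned after 75th percentile scaling (3924 higher and 3494 lower), with the mean of probe sets (3606 and 3456) and with the beta-actin covariate (3378 and 2727).

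On days 60 and 90 caudal LC kept Fcrl2 (5.79, SE 0.17, 2 of 2 days, adjusted p = 7.0e-32), Clec7a (5.53, SE 0.18) and Cd68 (5.07, SE 0.26) up and Scd (-2.97, SE 0.11, 2 of 2 days, adjusted p = 9.7e-27) and Idi1 (-2.25, SE 0.14) down. The neurotrophin gene Bdnf (-0.88, SE 0.16, 2 of 2 days, adjusted p = 5.9e-06) had fallen below uninjured cord. The inhibitory transporter gene Slc32a1 (-1.57, SE 0.20) and the synapsin gene Syn1 (-1.22, SE 0.16) fell. Microglia and macrophage genes rose (22 of 23 higher, 23 adjusted over the list alone, mean 2.32, adjusted p = 4.4e-25), and antigen presentation genes too (16 of 16 higher, mean 1.46, adjusted p = 6.7e-11). Cholesterol synthesis genes fell (16 of 16 lower, mean -1.54, adjusted p = 1.6e-16). The developmental genes Sox4 (1.17, SE 0.12) and Fabp7 (0.93, SE 0.08) rose. In limma 6820 genes were called, 3031 higher and 3789 lower, with 772 rising and 322 falling at least 2-fold. With the beta-actin covariate the split was 2579 higher and 2211 lower, and after 75th percentile scaling 3585 and 3241.

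**Figure D1:**
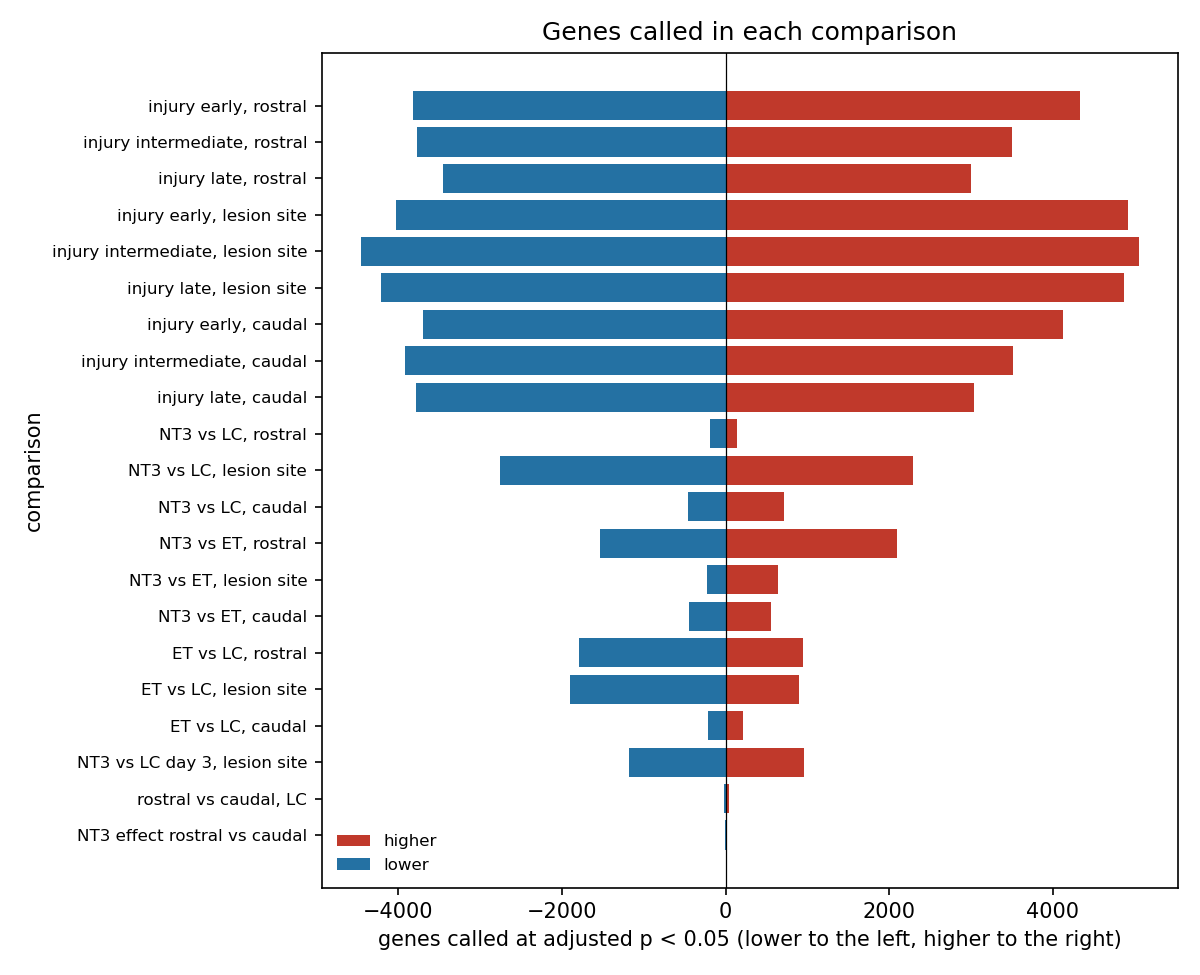
Number of genes called higher and lower in each comparison at an adjusted p below 0.05. The comparisons share controls, so their overlap is not shown.

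The class I gene RT1-CE10, which differs between rat strains and was chosen after its values were seen, split the arrays by whole groups. It stood above 9 in 58 arrays and at or below 9 in 109, with all arrays above in 17 groups, none in 35 and some in 4. On day 1 rostrally it was 6.74 (SD 0.10) with NT3, 10.84 (SD 0.15) with ET and 10.80 (SD 0.50) in LC, with n = 3 each, and 6.58 (SD 0.09) in uninjured cord. In 20 of 21 combinations of treatment and day, as many rostral as caudal arrays stood above 9. Comparisons between treatments averaged over days, the tests by day and the NT3 effect between segments were therefore repeated over days of like RT1-CE10, an alternative chosen after seeing the data. Those of day 3 at the lesion site, rostral against caudal LC and LC against uninjured cord were not. No uninjured array stood above 9, while all 3 LC arrays did on days 1, 30 and 90 rostrally and caudally. At the lesion site all 3 did on days 30 and 90 and 2 of 3 on days 3 and 20. No NT3 or ET array did there on day 3, nor any rostral or caudal LC array on day 20. Every injury period thus held LC arrays unlike the uninjured cords in this gene. With array weights, 13 counts of treatment and segment comparisons rose by more than 1.5 times, to between 154 and 10113.

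**Figure D2:**
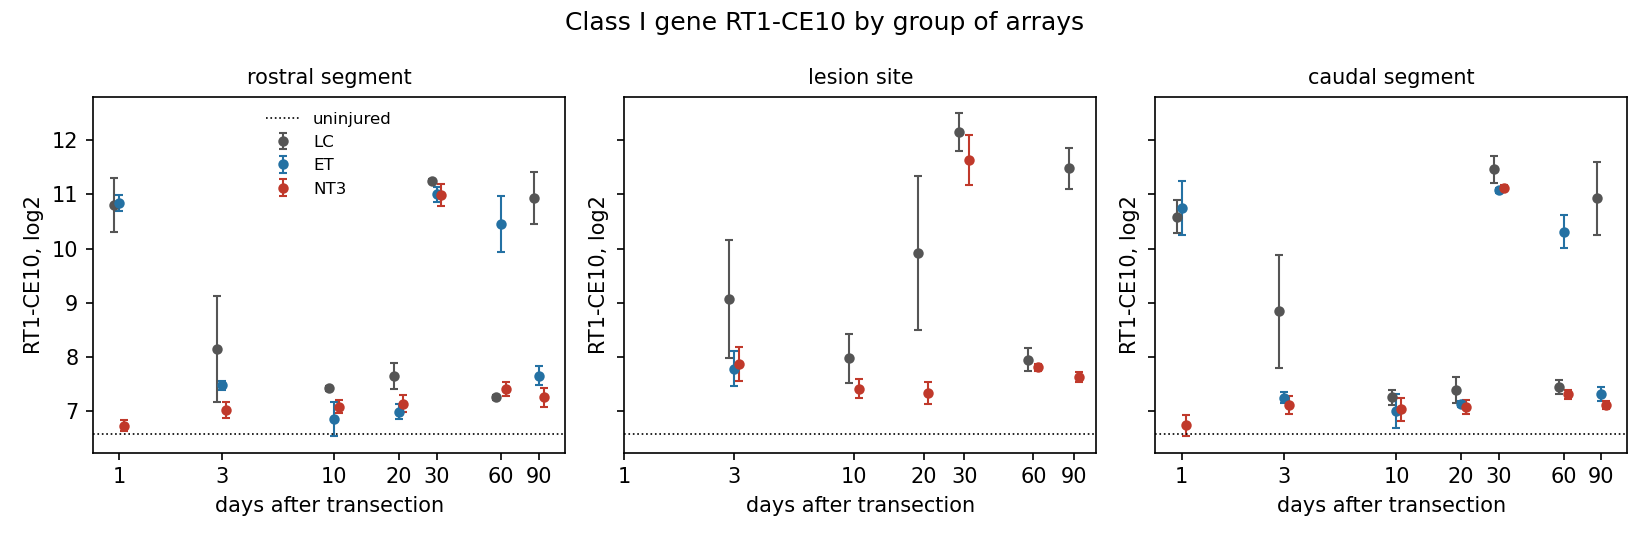
Level of RT1-CE10 in each group, in log2, as mean with SD over the 2 or 3 arrays of the group. The dotted line is the mean of the uninjured cords.

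With NT3 the rostral segment differed little from LC over the 7 days. The haem-degrading gene Hmox1 (-0.55, SE 0.07, 5 of 7 days, adjusted p = 2.5e-07) and the chemokine genes Cxcl1 (-0.76, SE 0.17, 6 of 7 days, adjusted p = 0.00919) and Ccl2 (-0.50, SE 0.11, 6 of 7 days, adjusted p = 0.00875) were lower. So was the cytokine signalling gene Socs3 (-0.24, SE 0.05). The positional gene Hoxa9 (0.42, SE 0.05, 7 of 7 days, adjusted p = 1.1e-06) and the neuronal gene Tmem215 (0.35, SE 0.07, 7 of 7 days, adjusted p = 0.00378) were higher. The peripheral myelin gene Pmp2 (-0.42, SE 0.08, 7 of 7 days, adjusted p = 0.00126) and the class I gene RT1-CE12 (-0.61, SE 0.05, 7 of 7 days, adjusted p = 1.7e-13) were lower. Cytokine genes were lower as a list (4 of 21 lower, 14 adjusted over the list alone, mean -0.27, adjusted p = 9.3e-07, or 0.29 with an estimated correlation). T cell genes were lower (3 of 13 lower, 8 adjusted over the list alone, mean -0.15, adjusted p = 1.8e-04, or 0.29 with an estimated correlation), and so were interferon genes (0 of 19 called, mean -0.13, adjusted p = 0.00766, or 0.545 with an estimated correlation). Dorsal root ganglion neuron genes stood higher (0 of 11 called, 7 higher adjusted over the list alone, mean 0.26, adjusted p = 6.4e-06, or 0.29 with an estimated correlation). The neurotrophin receptor gene Ntrk3 (0.20, SE 0.06, 6 of 7 days, adjusted p = 0.0612), Gfap (-0.02, SE 0.02, 5 of 7 days, adjusted p = 0.678) and Cd68 (-0.17, SE 0.09, 4 of 7 days, adjusted p = 0.285) were not called. In limma 333 genes were called, 139 higher and 194 lower, 1 of them lower by at least 2-fold. With days 10 to 90 alone 31 genes were called, and over the 4 days of like RT1-CE10 it was 58, and the larger direction turned in both (18 higher and 13 lower, 39 and 19). Under both, the calls of Hmox1 (-0.15 and -0.13), Cxcl1 (-0.54 and -0.42), Ccl2 (-0.38 and -0.22) and Socs3 (-0.17 and -0.16) ended. Over the like days those of RT1-CE12 (-0.15) ended too, and so did those of the cytokine, T cell and interferon lists. The number ran from 156 without LC day 1 replicate 3 to 750 without LC day 3 replicate 2. In all, 12 of 42 libraries moved it by more than 1.5 times.

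The rostral difference between NT3 and LC changed with the day for Hmox1, which was 11.58 (SD 0.24) with NT3 and 13.22 (SD 0.13) in LC on day 1. It was 9.94 (SD 0.06) against 10.18 (SD 0.01) on day 90, each with n = 3. The neuron list lay at -0.43 (SD 0.09) from uninjured cord with NT3 and at -0.95 (SD 0.12) in LC on day 1, and at -0.92 (SD 0.08) and -0.70 (SD 0.06) on day 60. The GABA synthesis gene Gad1 (adjusted p = 3.7e-05) and the endothelial nitric oxide synthase gene Nos3 (adjusted p = 2.7e-07) were among the genes whose difference moved with the day, and Hmox1 had an adjusted p of 2.7e-07. Gfap (adjusted p = 0.268) and Ntrk3 (adjusted p = 0.171) were not. The moderated F-test of limma called 3399 genes. Over the 4 days of like RT1-CE10, which leave out days 1 and 3, it called 0, with 1327 at an unadjusted p below 0.05, and the calls of Hmox1, Gad1 and Nos3 ended. By single days, NT3 and LC differed in 3691 genes on day 1, 854 on day 3 and 618 on day 90, when RT1-CE10 differed as well, and in 1, 17 and 43 on days 20, 30 and 60. On day 10 limma called 0 genes, with 645 at an unadjusted p below 0.05. The day 1 count was 2160 without LC replicate 3. On day 3 it was 97, 1975 and 439 without LC replicates 1, 2 and 3, of which replicate 2 had high RT1-CE10, and 376 and 278 without NT3 replicates 1 and 3. On day 90 it was 166, 58 and 224 without NT3 replicates 1, 2 and 3, and 127, 77 and 117 without LC replicates 1, 2 and 3. With any array of days 10 to 60 left out, at most 70 genes were called on its day.

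At the lesion site NT3, after day 3 inseparable from its tube, set apart inflammation and nerve tissue genes. The matrix protease gene Mmp3 (-3.40, SE 0.23, 6 of 6 days, adjusted p = 2.4e-13) and the neutrophil chemokine gene Cxcl2 (-2.22, SE 0.17, 6 of 6 days, adjusted p = 5.3e-12) were far lower than in LC, with the complement genes C3 (-1.73, SE 0.16) and C6 (-1.83, SE 0.11). The migrating neuroblast gene Dcx (1.24, SE 0.08, 6 of 6 days, adjusted p = 1.7e-13), the neural stem cell gene Sox2 (0.86, SE 0.10, 6 of 6 days, adjusted p = 2.4e-08) and the sensory peptide gene Calca (1.66, SE 0.30, 5 of 6 days, adjusted p = 3.4e-05) were higher. The neurofilament gene Nefh (1.45, SE 0.29) and the neurotrophin receptor gene Ngfr (0.84, SE 0.12) were too. The contractile gene Acta1 (3.68, SE 0.48, 6 of 6 days, adjusted p = 2.6e-07) and the myosin gene Myh2 (3.55, SE 0.48) were higher as well.

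Cytokine genes were lower as a list (1 higher and 18 lower of 21, mean -0.95, adjusted p = 1.8e-11). Complement genes were lower too (10 of 12 lower, mean -0.57, adjusted p = 2.0e-06). T cell genes followed (11 of 13 lower, mean -0.53, adjusted p = 3.2e-07, or 0.0711 with an estimated correlation), for instance Cd3e (-1.04, SE 0.09). Antigen presentation genes did the same (14 of 16 lower, mean -0.46, adjusted p = 2.9e-08, or 0.0711 with an estimated correlation), with RT1-DMb (-0.64, SE 0.05). Hypoxia genes were lower (14 of 18 lower, mean -0.42, adjusted p = 3.9e-09, or 0.0711 with an estimated correlation), with Ldha (-0.56, SE 0.04). Cell cycle genes stood lower (21 of 25 lower, mean -0.26, adjusted p = 2.0e-07, or 0.145 with an estimated correlation). Microglia and macrophage genes followed (1 higher and 13 lower of 23, mean -0.32, adjusted p = 1.9e-05, or 0.215 with an estimated correlation). Matrix genes were lower in part (15 of 25 lower, 1 higher and 15 lower adjusted over the list alone, mean -0.19, adjusted p = 8.9e-04, or 0.243 with an estimated correlation), with the fibronectin gene Fn1 (-0.60, SE 0.05). That list had no call when all samples shared one fit or over the 3 days of like RT1-CE10.

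Neuron genes were higher (19 of 22 higher, mean 0.83, adjusted p = 2.7e-08, or 0.215 with an estimated correlation). Dorsal root ganglion neuron genes were higher (10 of 11 higher, 11 adjusted over the list alone, mean 0.99, adjusted p = 7.2e-06, or 0.215 with an estimated correlation), with the sensory channel genes Trpv1 (1.05, SE 0.17) and Scn11a (1.06, SE 0.20). Motor neuron genes rose with them (7 of 10 higher, mean 0.84, adjusted p = 5.0e-04, or 0.215 with an estimated correlation). The GABA synthesis gene Gad1 (0.90, SE 0.21) was higher and lost its call over the days of like RT1-CE10 (0.46). Myelin genes were higher (15 of 19 higher, mean 0.51, adjusted p = 6.0e-06, or 0.243 with an estimated correlation), with Mobp (1.11, SE 0.20). So were Schwann cell genes (5 higher and 1 lower of 11, mean 0.25, adjusted p = 0.025, or 0.359 with an estimated correlation), with Sox10 (0.57, SE 0.10). Endothelial genes were mostly higher (13 higher and 4 lower of 22, mean 0.18, adjusted p = 0.00128, or 0.215 with an estimated correlation), with the capillary gene Emcn (0.78, SE 0.06). Every one of the skeletal muscle genes was higher (20 of 20 higher, mean 2.14, adjusted p = 5.2e-12, or 0.173 with an estimated correlation). Erythrocyte genes moved with them (5 of 7 higher, mean 0.59, adjusted p = 0.00181, or 0.215 with an estimated correlation). Neurotrophic factor genes were higher (8 higher and 1 lower of 15, 8 higher and 3 lower adjusted over the list alone, mean 0.27, adjusted p = 0.0155, or 0.215 with an estimated correlation), with Gfra1 (0.55, SE 0.06) and Ntrk2 (0.58, SE 0.13). Their list had no call when dim genes were kept or over the days of like RT1-CE10. Progenitor genes were higher (9 higher and 2 lower of 15, 9 higher and 3 lower adjusted over the list alone, mean 0.27, adjusted p = 0.00601, or 0.145 with an estimated correlation), and lost their call with the mean of probe sets.

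Several lists were not called. Among them were the proteoglycan list (5 higher and 5 lower of 12, mean 0.10, adjusted p = 0.898) and the astrocyte list (5 higher and 4 lower of 17, mean 0.15, adjusted p = 0.497). The precursor list was not called (5 higher and 3 lower of 8, mean 0.27, adjusted p = 0.348), nor was the axon growth list (12 higher and 6 lower of 23, mean 0.15, adjusted p = 0.078). The adipocyte list (3 higher and 2 lower of 7, mean 0.22, adjusted p = 0.263) and the interferon list (5 higher and 3 lower of 19, mean 0.10, adjusted p = 0.263) had no call. The cholesterol list had none either (2 higher and 1 lower of 16, 1 higher and 1 lower adjusted over the list alone, mean 0.03, adjusted p = 0.589). The neutrophil list had a mean of 0.16 and a median of 0.62 but a lower direction in the test (5 higher and 4 lower of 9, mean 0.16, adjusted p = 0.969). Gfap (0.37, SE 0.18, 5 of 6 days, adjusted p = 0.094), Cd68 (-0.10, SE 0.06, 4 of 6 days, adjusted p = 0.179), Aif1 (0.05, SE 0.09, 2 of 6 days, adjusted p = 0.686) and Bdnf (0.06, SE 0.08, 3 of 6 days, adjusted p = 0.562) were not called. In limma 5044 genes were called, 2291 higher and 2753 lower, with 142 higher and 71 lower by at least 2-fold. Over the 3 days of like RT1-CE10 the split was 1878 and 1776.

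**Figure D3:**
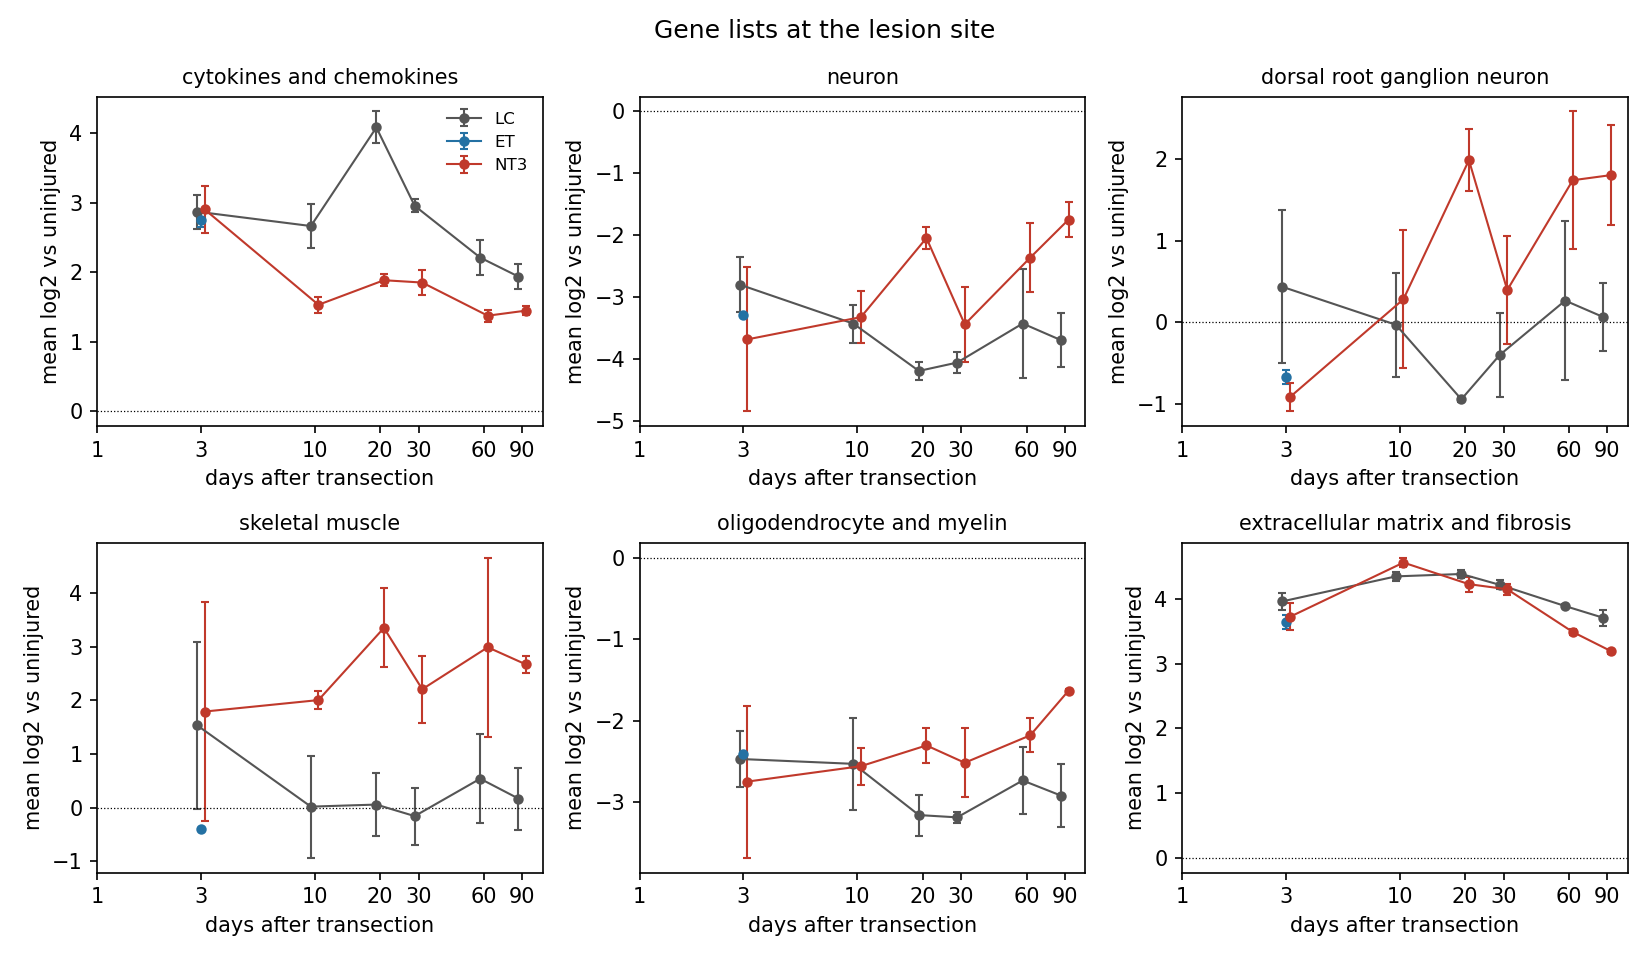
Mean of 6 gene lists at the lesion site relative to uninjured cord, in log2, as mean with SD over 3 arrays. ET was sampled on day 3 alone.

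The lesion-site difference between NT3 and LC changed with the day for several genes, and on days 3, 20 and 90 RT1-CE10 was unlike, with arrays above 9 in LC alone. On day 20, 1 LC array, replicate 5, also stood apart. Cxcl2 was 9.29 (SD 1.12) with NT3 and 11.64 (SD 0.77) in LC on day 3. It was 5.19 (SD 0.51) against 9.38 (SD 0.44) on day 20, with n = 3 in each group. On days 10 and 60, of like RT1-CE10, it was 4.93 (SD 0.29) against 7.98 (SD 0.88) and 5.40 (SD 0.13) against 5.95 (SD 0.25). Mmp3 in LC went from 6.75 (SD 1.06) on day 3 to 11.85 (SD 0.69) on day 20, where it was 6.96 (SD 0.37) with NT3. On day 60 it was 7.06 (SD 0.70) with NT3 and 10.71 (SD 0.67) in LC. The list of cytokines and chemokines lay at 2.90 (SD 0.34) with NT3 and 2.87 (SD 0.24) in LC on day 3, and at 1.88 (SD 0.08) and 4.08 (SD 0.23) on day 20. It lay at 1.37 (SD 0.08) and 2.21 (SD 0.26) on day 60. The neuron list lay at -3.68 (SD 1.16) with NT3 and -2.79 (SD 0.44) in LC on day 3, and at -1.74 (SD 0.29) and -3.69 (SD 0.43) on day 90. On days of like RT1-CE10 it lay at -3.32 (SD 0.42) and -3.42 (SD 0.31) on day 10 and at -2.36 (SD 0.55) and -3.42 (SD 0.87) on day 60. The dorsal root ganglion neuron list reached 1.99 (SD 0.38) with NT3 on day 20 and 1.81 (SD 0.61) on day 90, against -0.95 (SD 0.03) and 0.06 (SD 0.42) in LC. It was 0.28 (SD 0.85) against -0.03 (SD 0.64) on day 10 and 1.74 (SD 0.84) against 0.27 (SD 0.97) on day 60. Calca (adjusted p = 1.5e-05), Cd68 (adjusted p = 8.6e-07) and Mmp12 (adjusted p = 2.1e-10) had differences that moved with the day. The moderated F-test of limma called 6094 genes. Over days 10, 30 and 60 it called 883, and the calls of Mmp3 (adjusted p = 0.617), Calca (adjusted p = 0.505) and Cd68 (adjusted p = 0.129) ended, while Cxcl2 (adjusted p = 0.0190) and Mmp12 (adjusted p = 6.0e-04) were called.

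Caudal to the lesion NT3 went with lower inflammation genes, among them Cxcl2 (-0.88, SE 0.10, 7 of 7 days, adjusted p = 6.4e-08), Hmox1 (-0.70, SE 0.12, 7 of 7 days, adjusted p = 1.7e-04) and the arginase gene Arg1 (-0.66, SE 0.10). The positional gene Hoxd9 (0.89, SE 0.14, 7 of 7 days, adjusted p = 4.8e-05) and the B cell chemokine gene Cxcl13 (0.92, SE 0.19, 7 of 7 days, adjusted p = 0.00191) were higher, the class I gene RT1-CE10 (-1.49, SE 0.10, 7 of 7 days, adjusted p = 6.7e-16) lower. Myelin genes were higher as a list (12 of 19 higher, 15 adjusted over the list alone, mean 0.16, adjusted p = 6.6e-10, or 0.116 with an estimated correlation), with the hydroxylase gene Fa2h (0.24, SE 0.05). Cholesterol synthesis genes were higher (9 of 16 higher, 13 adjusted over the list alone, mean 0.15, adjusted p = 4.1e-08, or 0.116 with an estimated correlation), with Fdft1 (0.20, SE 0.05). Motor neuron genes were higher (4 of 10 higher, mean 0.16, adjusted p = 2.3e-04, or 0.116 with an estimated correlation), and so were Schwann cell genes (4 of 11 higher, 5 adjusted over the list alone, mean 0.17, adjusted p = 4.6e-04, or 0.116 with an estimated correlation). Cytokine genes were lower (1 higher and 9 lower of 21, 1 higher and 11 lower adjusted over the list alone, mean -0.22, adjusted p = 4.8e-07, or 0.116 with an estimated correlation). Complement genes were lower too (1 higher and 6 lower of 12, 1 higher and 7 lower adjusted over the list alone, mean -0.18, adjusted p = 1.1e-04, or 0.193 with an estimated correlation), with C6 (-0.89, SE 0.14). Ntrk3 (0.01, SE 0.09, 4 of 7 days, adjusted p = 0.977), Snap25 (0.04, SE 0.04, 5 of 7 days, adjusted p = 0.572) and Gfap (0.00, SE 0.02, 3 of 7 days, adjusted p = 0.938) were not called. In limma 1175 genes were called, 712 higher and 463 lower, 1 of them lower by at least 2-fold. After 75th percentile scaling the split was 536 higher and 630 lower. The count was 679 without LC day 20 replicate 2 and 760 without LC day 10 replicate 3. Over the 4 days of like RT1-CE10 it was 236, and the calls of Cxcl2 (-0.37), RT1-CE10 (-0.25), Fa2h (0.23) and Fdft1 (0.17) ended.

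The caudal difference changed with the day for Cxcl2, which was 5.64 (SD 0.25) with NT3 and 8.55 (SD 0.41) in LC on day 3. It was 4.33 (SD 0.19) against 4.76 (SD 0.09) on day 90, with n = 3 each (adjusted p = 8.9e-06). The interleukin gene Il6 was 6.02 (SD 0.53) against 8.04 (SD 0.21) on day 3 (adjusted p = 7.1e-05). The complement gene C3 ran the other way, at 9.52 (SD 0.05) with NT3 and 8.58 (SD 0.20) in LC on day 3 (adjusted p = 0.00776). The moderated F-test of limma called 865 genes, 443 without LC day 3 replicate 1 and 509 without NT3 day 3 replicate 1. On days 1, 3 and 90 RT1-CE10 was unlike. Over the 4 days of like RT1-CE10 limma called 0 genes by day, with 1677 at an unadjusted p below 0.05, and all 3 calls named here ended. On day 10, of like RT1-CE10, Cxcl2 was 4.73 (SD 0.13) with NT3 and 5.26 (SD 0.31) in LC.

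Against ET, NT3 went with lower matrix and higher neuron genes rostrally. Postn (-1.34, SE 0.18, 7 of 7 days, adjusted p = 5.9e-07), Col1a1 (-0.93, SE 0.15, 7 of 7 days, adjusted p = 5.8e-06) and Fn1 (-0.81, SE 0.11) and the retinol receptor gene Stra6 (-1.30, SE 0.12) were lower. Gad1 (0.38, SE 0.05, 7 of 7 days, adjusted p = 1.4e-07), Bdnf (0.34, SE 0.06, 7 of 7 days, adjusted p = 5.4e-05) and the synapsin gene Syn2 (0.34, SE 0.06) were higher. Matrix genes were lower as a list (24 of 25 lower, 25 adjusted over the list alone, mean -0.58, adjusted p = 2.1e-19, or 0.117 with an estimated correlation). Immediate early genes were lower (14 of 18 lower, 16 adjusted over the list alone, mean -0.28, adjusted p = 3.4e-09, or 0.117 with an estimated correlation). Neuron genes were higher (21 of 22 higher, mean 0.29, adjusted p = 1.2e-12, or 0.117 with an estimated correlation). Motor neuron genes were higher (9 of 10 higher, 10 adjusted over the list alone, mean 0.28, adjusted p = 2.0e-04, or 0.123 with an estimated correlation), as were myelin genes (14 of 19 higher, 15 adjusted over the list alone, mean 0.15, adjusted p = 7.2e-06, or 0.204 with an estimated correlation). Skeletal muscle genes were lower (1 higher and 14 lower of 20, 1 higher and 16 lower adjusted over the list alone, mean -0.75, adjusted p = 4.1e-07, or 0.286 with an estimated correlation), with Mb (-1.38, SE 0.31) and Myh2 (-1.50, SE 0.30). In limma 3633 genes were called, 2096 higher and 1537 lower, 18 lower by at least 2-fold. The split was 1728 and 1761 after quantile normalization and 1609 and 2043 after 75th percentile scaling. Over the 5 days of like RT1-CE10 the count was 1954. Days 10 to 30 gave at most 37 genes each, the others 591 up to 2953 on day 90.

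On day 3 at the lesion site, with 3 arrays in each arm, interferon genes were higher with NT3 than with ET. The ubiquitin-like gene Isg15 (2.63, SE 0.42, adjusted p = 2.6e-04) and the antiviral genes Ifit2 (1.38, SE 0.17, adjusted p = 1.1e-05) and Oasl (1.41, SE 0.22) rose. The spermatid-associated gene Spetex2l1 (-2.25, SE 0.20, adjusted p = 1.5e-08) was lower. Isg15 stood at 10.59 (SD 1.00) with NT3, 7.95 (SD 0.20) with ET, 8.14 (SD 0.23) in LC and 7.96 (SD 0.26) in uninjured cord. Interferon genes were higher as a list (13 of 19 higher, 15 adjusted over the list alone, mean 1.06, adjusted p = 2.1e-13, or 0.106 with an estimated correlation). In limma 870 genes were called, 636 higher and 234 lower, with 54 higher and 5 lower by at least 2-fold. The split was 290 higher and 399 lower after quantile normalization, 229 and 519 after 75th percentile scaling, and 703 and 501 without the filter. The count was 321 without NT3 replicate 2, 322 without NT3 replicate 3, 2011 without NT3 replicate 1. It was 452 without ET replicate 2 and 348 without ET replicate 3, which had a beta-actin difference of 2.14, and with the beta-actin covariate it was 785. It was 150 with the muscle covariate, 1575 when all samples shared one fit, 2319 without the 3 libraries that stood apart and 509 with a replicate block. When the fit held no other group it was 0 in limma, with 2474 at an unadjusted p below 0.05, and the calls of all genes named here ended.

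Caudal to the lesion NT3 also went with lower matrix genes than ET, such as Postn (-1.05, SE 0.17, 7 of 7 days, adjusted p = 1.4e-04), Fn1 (-0.63, SE 0.10, 6 of 7 days, adjusted p = 1.4e-04) and Stra6 (-1.42, SE 0.17). The cartilage gene Cnmd (0.82, SE 0.13), the positional gene Hoxd9 (0.63, SE 0.14) and the peripheral myelin gene Pmp2 (0.62, SE 0.10, 7 of 7 days, adjusted p = 1.2e-04) were higher. Matrix genes were lower as a list (12 of 25 lower, 19 adjusted over the list alone, mean -0.34, adjusted p = 3.9e-14, or 0.244 with an estimated correlation). Motor neuron genes were higher (5 of 10 higher, 6 adjusted over the list alone, mean 0.18, adjusted p = 8.5e-04, or 0.244 with an estimated correlation). Schwann cell genes were as well (4 of 11 higher, mean 0.17, adjusted p = 0.00107, or 0.244 with an estimated correlation). In limma 1009 genes were called, 560 higher and 449 lower, 3 of them lower by at least 2-fold. The split was 398 and 518 after quantile normalization and 395 and 712 after 75th percentile scaling, and the larger direction also turned without ET day 10 replicate 2. The count ran from 593 without ET day 1 replicate 3 to 1555 without ET day 3 replicate 1. In all, 6 of 42 libraries moved it by more than 1.5 times.

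The empty tube set the rostral segment apart from LC in matrix genes. Postn (1.38, SE 0.18, 6 of 7 days, adjusted p = 3.1e-07), Col1a1 (1.06, SE 0.15, 7 of 7 days, adjusted p = 8.1e-07) and the collagen-linked gene Cthrc1 (1.05, SE 0.12) were higher. Gad1 (-0.36, SE 0.05, 5 of 7 days, adjusted p = 1.8e-07), Chat (-0.54, SE 0.07, 6 of 7 days, adjusted p = 8.2e-07) and the motor neuron gene Chodl (-0.56, SE 0.07) were lower. Matrix genes were higher in nearly every member (24 of 25 higher, 25 adjusted over the list alone, mean 0.60, adjusted p = 2.1e-28, or 0.116 with an estimated correlation). Neuron genes were lower (18 of 22 lower, 20 adjusted over the list alone, mean -0.24, adjusted p = 1.5e-09, or 0.247 with an estimated correlation). Motor neuron genes were lower (6 of 10 lower, 7 adjusted over the list alone, mean -0.33, adjusted p = 9.8e-06, or 0.116 with an estimated correlation). Muscle genes were higher (11 higher and 1 lower of 20, 14 higher and 1 lower adjusted over the list alone, mean 0.65, adjusted p = 1.9e-07, or 0.462 with an estimated correlation), with Myl1 (1.98, SE 0.44) and Myh2 (1.47, SE 0.30). The mean of the muscle list with ET varied from -0.41 (SD 0.07) on day 10 to 1.30 (SD 2.17) on day 30. In limma 2741 genes were called, 951 higher and 1790 lower, 26 of them higher by at least 2-fold. After 75th percentile scaling the split was 1309 and 1093. Over the 4 days of like RT1-CE10 the count was 493, 300 higher and 193 lower, and the calls of Myl1 (1.39) and Myh2 (0.97) ended.

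**Figure D4:**
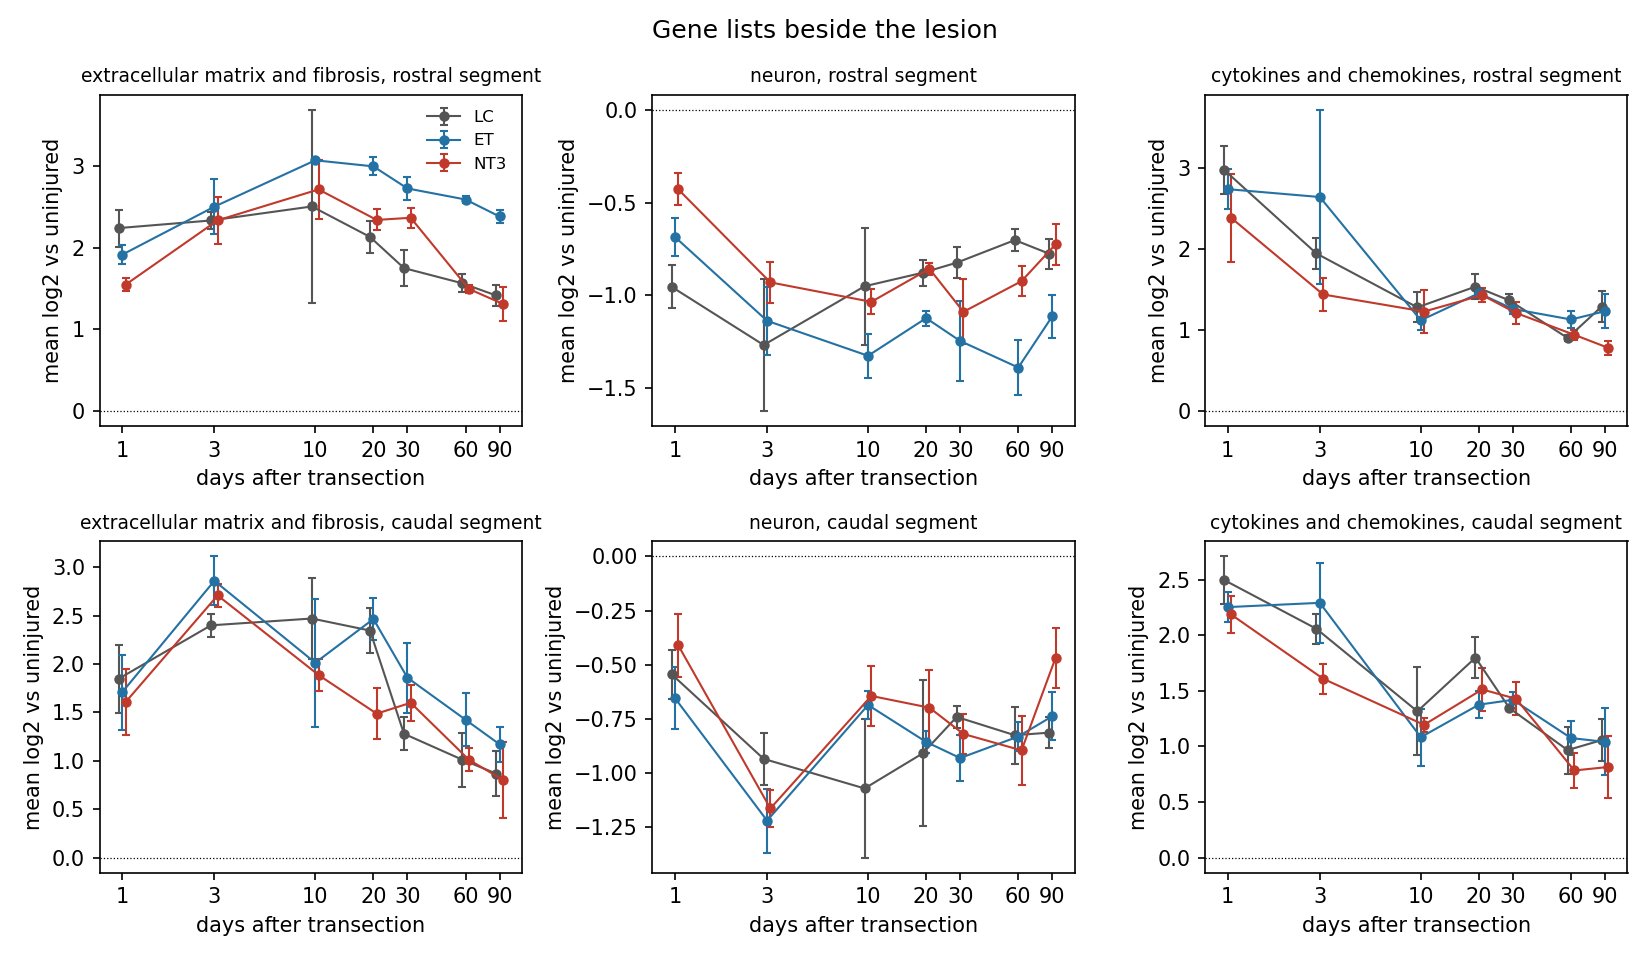
Mean of 3 gene lists in the rostral and caudal segments relative to uninjured cord, in log2, as mean with SD over the 2 or 3 arrays of each group.

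On day 3 the lesion site with ET, 3 arrays against 3 of LC, had higher macrophage genes. ET replicate 3 had a beta-actin difference between 3-prime and 5-prime probe sets of 2.14, against 0.98 and 0.94 in the other 2 ET arrays, and with the beta-actin covariate 2999 genes were called. Mmp12 (1.87, SE 0.22, adjusted p = 9.1e-07), Cd68 (0.92, SE 0.15, adjusted p = 3.7e-05) and the microglial gene Aif1 (1.07, SE 0.22, adjusted p = 8.6e-04) were higher. The Schwann cell genes Pmp2 (-2.32, SE 0.26, adjusted p = 3.6e-07) and Drp2 (-1.93, SE 0.26) were lower. Microglia and macrophage genes were higher as a list (15 of 23 higher, 18 adjusted over the list alone, mean 0.48, adjusted p = 1.4e-10, or 0.294 with an estimated correlation). Antigen presentation genes were higher too (7 higher and 1 lower of 16, 9 higher and 1 lower adjusted over the list alone, mean 0.37, adjusted p = 4.5e-05, or 0.546 with an estimated correlation). Schwann cell genes were lower (6 of 11 lower, 8 adjusted over the list alone, mean -1.01, adjusted p = 7.7e-04, or 0.635 with an estimated correlation). In limma 2794 genes were called, 892 higher and 1902 lower, with 27 higher and 186 lower by at least 2-fold. The split was 1366 and 1166 after quantile normalization, 1521 and 1113 after 75th percentile scaling and 1415 and 1929 without the filter. It was 1832 genes in all when the fit held no other group.

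Caudal to the lesion the clock gene Per2 (0.39, SE 0.08, 7 of 7 days, adjusted p = 0.0112) and the smooth muscle gene Actg2 (0.33, SE 0.07, 7 of 7 days, adjusted p = 0.0133) were higher with ET than in LC. The costimulatory gene Cd86 (-0.27, SE 0.06, 7 of 7 days, adjusted p = 0.0118) and the osteopontin gene Spp1 (-0.35, SE 0.08, 6 of 7 days, adjusted p = 0.0133) were lower. Microglia and macrophage genes were lower as a list (4 of 23 lower, 8 adjusted over the list alone, mean -0.13, adjusted p = 5.4e-05, or 0.716 with an estimated correlation). T cell genes were lower (1 of 13 lower, 5 adjusted over the list alone, mean -0.13, adjusted p = 0.00412, or 0.716 with an estimated correlation). In limma 422 genes were called, 207 higher and 215 lower, and the larger direction turned under several alternatives, such as 75th percentile scaling (344 and 279) and the days of like RT1-CE10 (987 and 668), and with several arrays left out one at a time. The count ran from 159 without ET day 1 replicate 3 to 1092 without ET day 1 replicate 2. In all, 18 of 42 libraries moved it by more than 1.5 times. It was 271 with the mean of probe sets, 99 higher and 172 lower, and 165 when the fit held no other group. With the beta-actin covariate it was 640, and over the 4 days of like RT1-CE10 it was 1655, where the call of Per2 (0.28) ended.

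On day 3 alone, with 3 arrays in each arm, the lesion site with NT3 had higher interferon genes than LC. The helicase gene Ddx60 (2.74, SE 0.35, adjusted p = 1.3e-06), Isg15 (2.45, SE 0.42, adjusted p = 9.8e-05) and the deubiquitinase gene Usp18 (1.79, SE 0.20) rose. The ciliary neurotrophic factor gene Cntf (-1.79, SE 0.26, adjusted p = 1.3e-05), Pmp2 (-1.76, SE 0.26) and the extracellular gene Coch (-2.52, SE 0.35) fell. Interferon genes were higher as a list (13 of 19 higher, 14 higher and 1 lower adjusted over the list alone, mean 0.96, adjusted p = 1.9e-09, or 0.186 with an estimated correlation). Antigen presentation genes were higher (12 of 16 higher, 13 adjusted over the list alone, mean 0.53, adjusted p = 8.8e-08, or 0.186 with an estimated correlation), and T cell genes too (7 of 13 higher, 8 adjusted over the list alone, mean 0.57, adjusted p = 3.1e-05, or 0.204 with an estimated correlation). Schwann cell genes were lower (6 of 11 lower, 8 adjusted over the list alone, mean -0.96, adjusted p = 1.2e-05, or 0.204 with an estimated correlation). Neurotrophic factor genes followed (6 of 15 lower, 7 adjusted over the list alone, mean -0.49, adjusted p = 0.00544, or 0.286 with an estimated correlation). Snap25 (-1.70, SE 0.69, adjusted p = 0.0868) was not called. In limma 2142 genes were called, 960 higher and 1182 lower, with 73 higher and 174 lower by at least 2-fold. The count was 1290 without LC replicate 2, 1306 without NT3 replicate 2 and 540 when the fit held no other group.

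Rostral and caudal segments of LC were close to each other. The positional genes Hoxa10 (-1.25, SE 0.13, 7 of 7 days, adjusted p = 5.9e-11) and Hoxa9 (-0.66, SE 0.05, 7 of 7 days, adjusted p = 5.5e-17) were lower rostrally, and Pmp2 (0.67, SE 0.09, 7 of 7 days, adjusted p = 1.8e-07) was higher. Matrix genes stood slightly higher rostrally (1 of 25 higher, 14 adjusted over the list alone, mean 0.25, adjusted p = 2.3e-13, or 0.385 with an estimated correlation). Neuron genes stood slightly lower (0 of 22 called, 6 lower adjusted over the list alone, mean -0.07, adjusted p = 1.0e-07, or 0.403 with an estimated correlation). Cholesterol synthesis genes stood higher rostrally (1 of 16 higher, 5 adjusted over the list alone, mean 0.10, adjusted p = 1.5e-08, or 0.0687 with an estimated correlation). In limma 61 genes were called, 47 higher and 14 lower, 1 of them lower by at least 2-fold. The count ran from 31 without rostral LC day 10 replicate 3 to 190 without rostral LC day 10 replicate 1. In all, 8 of 42 libraries moved it by more than 1.5 times. It was 26 when the fit held no other group.

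The difference of NT3 from LC was compared between the rostral and the caudal segment. It was more negative rostrally for Pmp2 (-0.85, SE 0.13, 6 of 7 days, adjusted p = 2.4e-05) and for Chat (-0.46, SE 0.10, 5 of 7 days, adjusted p = 0.0158), the latter without a call when the beta-actin difference was a covariate. Motor neuron genes followed (3 of 10 lower, 6 adjusted over the list alone, mean -0.21, adjusted p = 1.1e-05, or 0.103 with an estimated correlation). Complement genes were less negative rostrally (0 of 12 called, 2 higher and 1 lower adjusted over the list alone, mean 0.14, adjusted p = 1.1e-05, or 0.103 with an estimated correlation). In limma 13 genes were called, 2 higher and 11 lower. After 75th percentile scaling it was 6, 2 higher and 4 lower. The count ran from 4 without caudal NT3 day 1 replicate 2 to 19 without caudal NT3 day 1 replicate 1. In all, 32 of 84 libraries moved it by more than 1.5 times. Over the 4 days of like RT1-CE10 it was 529, 135 higher and 394 lower, and with the beta-actin covariate it was 4.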

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

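The difference between NT3 and LC changed with the day for 3399 genes rostrally, 6094 at the lesion site and 865 caudally, and differed between the rostral and the caudal segment for 13. Over the days of like RT1-CE10 the tests by day called 883 genes at the lesion site and, in limma, 0 rostrally and caudally, with 1327 and 1677 at an unadjusted p below 0.05. These counts stand out because the same contrast differed between days or segments by a test of the difference itself. Among probe sets with no gene name, which the report leaves aside, 3961 of 5430 were called in LC against uninjured cord at the lesion site on days 10 to 30, and 1707 in NT3 against LC there, a signal outside the measurements reported on.

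In this part the tests chosen only after the result was seen are all those on days of like RT1-CE10 and on day 90, those on the dorsal root ganglion list and on genes of spinal inhibitory and cholinergic neurons alone, the test on immune genes, those with the actin covariate, and all splits of the samples. The tests on the share of the loss regained, with the muscle covariate in the rostral segment and on day 3 were chosen after the data were seen but before their own results were.

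Neuron and dorsal root ganglion genes were higher with NT3 than in LC at the lesion site. The ganglion list lay 1.24 (SE 0.38) above uninjured cord with NT3 on days 10 to 90. Ganglion or nerve root RNA and growth of sensory axons cannot be told apart for this list, because the design holds no sample of either. Rostral cord was excluded as its whole cause, since the list lay 0.50 (SE 0.17) above the rostral segment. Caudal cord was not tested for this list. Ganglion RNA was excluded as the whole cause for 5 genes of spinal inhibitory and cholinergic neurons, which were 0.62 (SE 0.13) higher with NT3 than in LC. Neighbouring cord stays open for the neuron list. Its members regained a median of 12.4 percent of their loss (quartiles 6.07 and 19.2). The 5 spinal genes regained 2.29 (2.16 and 4.84) and the myelin list 7.89 percent (5.68 and 11.6). The loss was set against uninjured cord, while neighbouring cord was injured. RNA quality was excluded as the whole cause, since all 19 called members were called beside the actin covariate too (list mean 0.83). The actin difference was 1.15 (SD 0.21) with NT3 and 1.17 (SD 0.22) in LC. Over the 3 days of like RT1-CE10 the list was 0.59 (SE 0.24) higher, yet cohorts can share a level, so rats of another cohort stay open. Sensory axons in the tube, or ganglia and roots taken with it, stay as hypotheses that staining of labelled ganglion neurons there would test. The tube alone stays open too. The muscle list was 2.14 higher, yet beside a muscle covariate the neuron and ganglion lists stayed 1.14 and 1.17 higher.

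Matrix genes were higher and neuron genes lower with ET than in LC in the rostral segment. Lesion tissue taken with the segment stays open, since the lesion site of ET was not sampled after day 3, and against the lesion site of LC immune genes moved by a median of 0.353 percent of the way to the lesion-site level (quartiles -1.57 and 3.82, 34 genes), against 19.1 percent for the matrix list and 29.9 percent for the neuron list. Muscle RNA was excluded as the whole cause for the matrix list, since 22 of its 24 members called higher were called beside the muscle covariate too, with a list mean of 0.59. Rats of another cohort stay open for the matrix list, though it was 0.52 (SE 0.13) higher over the 4 days of like RT1-CE10. A segment taken nearer the tube and a fibrous reaction to the empty tube stay open. Collagen staining of sections at a known distance from it would test the latter hypothesis.

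RT1-CE10 stood high or low in whole groups of arrays, as it would if rats of another stock or cohort made up some groups. For NT3 against LC rostrally this explanation could hold, with 58 genes over the 4 days of like RT1-CE10 and 3579 over the other 3. Day 3 leaves it open, with 854 genes, 1975 without the LC array of high RT1-CE10 and 97 without LC replicate 1 (actin difference 1.81). The acute response of days 1 and 3 cannot be told apart from it as the cause, since day 90 called 618 genes where days 10 to 60 called at most 43, but 58 to 224 with 1 array left out, where day 60 reached 70 without NT3 replicate 3, and an effect of NT3 itself stays open, confounded with the level of RT1-CE10 on days 1 and 90. Caudally, 236 against 654 genes leave it open. At the lesion site 3654 genes called over days of like RT1-CE10, against 4915, exclude its level but not cohort as the whole cause. For ET against LC caudally, 1655 genes over the days of like RT1-CE10, 2233 on day 1 alone, and 38 over the others decide nothing, since RT1-CE10 differed by 2.86 on day 60 and by -3.61 on day 90.

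Other splits of the same arrays called fewer genes than the real grouping in most comparisons, which argues against chance if arrays are independent. Here only the real one of 84 or 100 splits reached the real count. For LC against uninjured cord the highest other split called 6156, 5170 and 4379 against 8157, 7281 and 6453 genes rostrally. It called 7248 and 6753 against 9511 and 9083 on intermediate and late days at the lesion site. Caudally it was 6183, 4936 and 4504 against 7829, 7427 and 6820. For NT3 against LC it was 1700 against 5044 at the lesion site and 308 against 1175 caudally. By day it was 1573, 2757 and 452 against 3399, 6094 and 865. For NT3 against ET it was 1177 against 3633 rostrally and 4 against 1009 caudally. For ET against LC it was 929 against 2741 rostrally. Caudally, 406 against 422 leaves chance open.

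In 3 comparisons the share of splits that reached the real count was under 0.05, but some other splits called more genes than the real grouping. These were NT3 against LC rostrally (3 of 100 splits, highest other 704 against 333) and rostral against caudal LC (4 of 100, 1028 against 61). The third was the NT3 effect between segments (4 of 100, 1957 against 13). Chance is not settled by the splits there. Why some splits called several times the real count was not tested. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. There the real and the highest other count were 8952 and 3 for early injury at the lesion site, 870 and 223 for NT3 against ET, 2794 and 2 for ET against LC, and 2142 and 1292 for NT3 against LC on day 3.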

How the results depend on the processing

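The covariates, the removal of the 3 arrays that stood apart and the days of like RT1-CE10 were chosen only after the data were seen. Of 24 counts of called genes, each stayed within 1.5 times its value with no filter, with the stricter filter, with quantile normalization and with the trended and robust prior. Other counts moved, and the cause was not tested except where fewer days or samples give it. With 75th percentile scaling the NT3 effect between segments was 6, and with the mean of probe sets ET against LC caudally was 271. With one fit of all arrays NT3 against ET at the lesion site was 1575. With the compared groups alone, which leaves fewer samples for the spread, limma called 0 genes for NT3 against ET at the lesion site, with 2474 at an unadjusted p below 0.05. It called 1832 for ET against LC there, 165 for ET against LC caudally, 540 for NT3 against LC on day 3 and 26 for rostral against caudal LC.

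With array weights counts rose to 1639 and 2973 for NT3 against LC rostrally and caudally, 9590, 10113 and 8039 by day rostrally, at the lesion site and caudally. They rose to 5803, 3954 and 2785 for NT3 against ET in the same order, 4234 and 1722 for ET against LC at the lesion site and caudally, 3471 on day 3, 288 for rostral against caudal LC and 154 for the NT3 effect between segments. With the actin covariate ET against LC caudally was 640 and the NT3 effect between segments 4. For NT3 against ET at the lesion site it was 2319 without the arrays that stood apart and 150 with the muscle covariate. With days 10 to 90 NT3 against LC rostrally was 31. Over the days of like RT1-CE10 counts were 58 and 236 for NT3 against LC rostrally and caudally, and 1954 for NT3 against ET rostrally. They were 493 and 1655 for ET against LC rostrally and caudally, and 529 for the NT3 effect between segments. By day they were 0 rostrally and caudally in limma, with 1327 and 1677 at an unadjusted p below 0.05, and 883 at the lesion site.

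Whether like replicate numbers mark 1 animal is not stated. Residuals of like numbers correlated above 0.1 in 54 of 147 pairs between treatments (mean 0.0256) and in 32 of 62 between the rostral and caudal segments (mean 0.0859). Between these segments an array correlated best with its own number in 28 of 62, and every pair exceeded 0.1 in 5 of 21 group pairs, so a pairing of segments stays open and none was assumed. With the replicate number as a block NT3 against ET at the lesion site was 509, and the other 23 counts stayed within 1.5 times.

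Leaving out 1 array gave, for injury on early, intermediate and late days, 7664 to 8183, 6425 to 7423 and 5563 to 6275 genes rostrally. It gave 8523 to 8685, 9024 to 9566 and 8540 to 9022 at the lesion site, and 7223 to 7816, 6583 to 7482 and 5722 to 6868 caudally. NT3 against LC ran from 156 to 750 rostrally, 4706 to 5281 at the lesion site and 679 to 1672 caudally. By day it ran from 2574 to 4720, 5378 to 6606 and 443 to 1242. NT3 against ET ran from 3249 to 3780, 321 to 2011 and 593 to 1555. ET against LC ran from 2227 to 3017, 1883 to 2447 and 159 to 1092. NT3 against LC on day 3 ran from 1290 to 2731, rostral against caudal LC from 31 to 190 and the NT3 effect between segments from 4 to 19.

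Of 192 named gene results, 179 called, 0 reversed in any alternative. Calls ended for 13 over the days of like RT1-CE10, for 4 with the compared groups alone, for 4 with days 10 to 90 and for 1 with the actin covariate, and 0 ended with any array left out. The genes named in the tests by day were not among these results. Of 118 list results, 103 called, 0 reversed, 81 lost their call with an estimated correlation and 5 over the days of like RT1-CE10. Genes below the 40th percentile of array signal, Ntf3 among them, were not tested.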

Other observations

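B and plasma cell genes were lower with NT3 than in LC at the lesion site (5 of 6 lower, mean -0.85, adjusted p = 0.00479, or 0.215 with an estimated correlation). The immunoglobulin joining chain gene Jchain (-1.15, SE 0.17), made by plasma cells, stood at 11.21 (SD 0.20) in LC on day 60 and at 8.65 (SD 0.58) with NT3, with n = 3 each. The lymphoid chemokine gene Ccl21, chosen after its values were seen, stood at 10.25 (SD 0.70) in the rostral segment with ET on day 90, at 7.11 (SD 0.93) with NT3 and at 6.22 (SD 0.41) in LC. The peripheral myelin gene Pmp2 stood at 8.11 (SD 0.50) with NT3, 7.54 (SD 0.56) with ET and 9.86 (SD 0.28) in LC at the lesion site on day 3.

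At the lesion site the cell cycle list lay 0.75 (SD 0.02) above uninjured cord in LC on day 90, and with NT3 3.45 (SD 0.05) on day 3 and 0.57 (SD 0.05) on day 90. The doublecortin gene Dcx stood at 7.44 (SD 0.09) in uninjured cord, 7.25 (SD 0.21) with NT3 on day 30 and 5.97 (SD 0.04) on day 90, against 4.87 (SD 0.30) in LC on day 90.

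Positional genes were lower in LC than in uninjured cord, and all tests on them were chosen only after this was seen. Over 5 genes of paralog groups 9 and 10 the difference was -1.65 (SE 0.18) rostrally and -1.08 (SE 0.19) caudally, and it exceeded that of 13 genes of groups 2 to 8 by -1.47 (SE 0.18) and -0.81 (SE 0.18), as it could if the uninjured cords came from a lower level of the cord. Groups 2 to 8 (-0.17, SE 0.05, neuron list -0.91, SE 0.09) need not mark the neurons of groups 9 and 10. Loss of neurons stays open. With the actin covariate the difference over groups 9 and 10 was -1.21 (SE 0.22) rostrally but -0.46 (SE 0.25) caudally. The same uninjured arrays served both, so their RNA quality stays open as a cause. Rostral LC lay -0.56 (SE 0.08) from caudal LC over groups 9 and 10. With NT3 these genes were higher than in LC by 0.27 (SE 0.09) rostrally, 0.35 (SE 0.09) at the lesion site and 0.46 (SE 0.10) caudally. The uninjured cords themselves varied, with Hoxa10 at 9.68 (SD 1.08) and Hoxd10 at 6.43 (SD 1.75), and an effect of injury on these genes stays open.

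One array, lesion site LC day 20 replicate 5, read 3.14 for the dap spike-in, where the next lowest array read 10.5.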
